A study of Homo sapiens with 6 samples.

How the data were processed

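RNA of 6 clones of HEK293 was hybridised to Affymetrix whole-transcript arrays, 1 array per clone, 3 clones with the empty vector pCI-neo and 3 with the vector carrying FLAG- and HA-tagged MIBP1. Per the labels' protocols, clones were picked after selection with G418 and kept under it, RNA quality was checked before labelling, and RNA was amplified as sense-strand target and biotinylated. Such stable clones descend from single transfected cells, so each carries its own integration and its own history, and a difference between 3 and 3 clones holds both.

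The deposited table holds 1 intensity on a linear scale per probe set and array, 33297 probe sets in all, with values from 2.22 to 26006.8. RMA, which corrects background, normalizes quantiles and summarises probes, and Affymetrix Expression Console 1.1.1 are named in the submitters' processing notes, without their roles or the chip library files. RMA normally ends on a log2 scale, while the deposited intensities are linear, so log2 was taken before any test, as the design written before the data were examined provided for. Array medians were 85.8 to 98.5 and quartile ranges 3.49 to 3.86 on the log2 scale, so the columns did not share 1 distribution. Per-probe signals, detection calls and the background are not analysed here, so dim genes were kept and differences near the floor are compressed. Column names were matched to samples by their identifiers, and 0 value columns were left without a sample.

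Gene names came from the platform annotation given for the table. It gave 19460 probe sets with 1 symbol, 1754 with several and 12083 with none; 19429 of the first kind matched a current gene by identifier and 0 symbols needed an update. For each gene the single-symbol probe set with the highest mean over the 6 arrays was used, which left 18417 genes, 769 of them with more than 1 probe set. Probe sets with several symbols were not named. No genome was used, and gene order came from the RefSeq annotation of the GRCh38.p14 assembly for neighbour relations alone.

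Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without an intensity trend or covariates, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Before the data were examined, 28 lists were fixed, 23 gene lists and 5 marker lists, with 768 distinct genes, of which 65 had no single-symbol probe set and 14 were looked up under a newer symbol. The 27 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, two-sided, adjusted over the lists. Camera compares a list with the other genes, and the preset correlation is small, so calls can rest on genes that move together from clone to clone; camera with an estimated correlation and fry, which tests a list on its own, were run beside it. With an estimated correlation camera also works from the 4 residual degrees of freedom of the arrays, so a call can be lost where the estimate is below the preset. Lists were also set against 10000 random lists of the same size matched on mean level in 20 bins. A deviation is a gene's value in an array minus its mean over the 6 arrays, averaged over a list. Per-gene values are means ± SD over 3 clones, and SE is limma's moderated standard error. All p are two-sided.

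The genes named were fixed by a rule. In each direction it takes up to 12 genes past the adjusted threshold with groups that do not overlap, filled with the smallest p where fewer pass, and as 0 passed, all 12 are genes that miss it. It adds HIVEP1, HIVEP2 and HIVEP3, and the 4 members with the smallest p of the NF-kB target list and of each list past its threshold. Members of families with near-identical copies are said to be uncertain, and genes outside the rule are said to be so.

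The alternatives, all but 2 fixed before the data were examined, were an intensity trend, genes at or above the median level, quantile normalization, median centring, array weights, the mean of a gene's probe sets, replicate numbers as a block, leaving out each clone, other thresholds, all probe sets, a test without variance moderation, and other list tests. The 2 added later were centring each value on the running median of its array over 101 neighbouring genes and the first residual component as a covariate. The steps were tested on simulated data with the real genes' means and spreads: among 18417 genes with 200 changed, 50% of 2-fold and 90% of 4-fold changes were called along with 4 unchanged genes, and 9 of 9 lists shifted by −0.3 and 0 of 18 unshifted lists were called. The simulated genes were independent, so the list result says nothing about genes that move together. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the figures.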

Results

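Gene expression was measured in 6 stable clones of HEK293, a human embryonic kidney cell line that also carries neuronal and adrenal transcripts. One group held 3 clones with the empty vector, and the other held 3 clones with the same vector carrying tagged MIBP1. MIBP1 is another name of HIVEP2, a large zinc finger protein that binds DNA motifs resembling those of NF-kB. Per the labels, each sample was a clone of its own, numbered 3, 6 and 11 with the empty vector and 31, 49 and 76 with MIBP1, and these are called replicates 1, 2 and 3 of their group. The spread between arrays therefore holds differences between clones. The median intensity per array ran from 85.8 to 98.5, and the correlation between arrays ran from 0.967 to 0.994 across genes, which are not independent replicates. The number of arrays limits the precision, and the median standard error of a log2 difference over the 18417 genes tested was 0.181. The comparison asks which genes and gene groups differ between clones with and without overexpressed MIBP1. Differences are log2 values of clones labelled MIBP1 minus empty vector clones, with n = 3 in each group.

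The probe set of HIVEP2, the gene that was overexpressed, was lower in all 3 clones labelled MIBP1 than in all 3 empty vector clones. Its mean log2 intensity was 8.66 ± 0.26 (SD, n = 3) with the empty vector and 7.61 ± 0.44 (SD, n = 3) in the clones labelled MIBP1. The empty vector clones gave 8.90, 8.38 and 8.71, and the clones labelled MIBP1 gave 7.77, 7.94 and 7.11. The difference was −1.05 (SE 0.23), with a limma adjusted p of 0.637 over all genes. Its paralog HIVEP1 was lower by a log2 difference of −0.92 (SE 0.16, limma adjusted p = 0.407), and HIVEP3 by −0.39 (SE 0.15, limma adjusted p = 0.843), again without overlap between the groups. None of the 3 passed over all genes, and 3 of 3 passed when adjusted over the list alone. Per the labels' protocols, integration and tagged protein were checked by PCR and immunoblot. Whether the probes lie in the transgene's transcript is not given in the sources used here, so the probe set may check nothing about the labels. The groups are called clones labelled MIBP1 for this reason, and every direction rests on the labels.

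Among the genes that were lower in the clones labelled MIBP1, the 12 with the smallest p all missed the adjusted threshold. LOXL2, an enzyme that cross-links collagen, had a log2 difference of −1.41 (SE 0.18), a 2.65-fold lower level. CPA4, a carboxypeptidase, was 3.66-fold lower (−1.87, SE 0.24), and COL12A1, a fibril-associated collagen, was 3.40-fold lower (−1.77, SE 0.23). These 3 genes had the smallest adjusted p of all, 0.126 in limma, which misses the threshold of 0.05. FN1, which encodes fibronectin and was among the brightest genes named, went from 12.21 ± 0.07 (SD, n = 3) to 11.12 ± 0.36 (SD, n = 3), a difference of −1.09 (SE 0.20). LAMB3, a laminin chain, gave −0.97 (SE 0.17). The ligands TGFB2 and TGFB1 gave −1.22 (SE 0.21) and −1.09 (SE 0.20), and NOG, a secreted antagonist of BMPs, gave −1.06 (SE 0.16). At the cell surface, the adhesion receptor ADGRG6 gave −0.98 (SE 0.16), CAV1, the coat protein of caveolae, gave −0.95 (SE 0.17), and OSMR, the oncostatin M receptor, gave −1.20 (SE 0.22). The adjusted p of these 9 further genes, HIVEP1 included, lay between 0.243 and 0.464. In each of the 12 the 3 clones labelled MIBP1 were all below the 3 empty vector clones. That adds little, as the 12 were picked for the smallest p on these arrays.

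**Figure D1:**
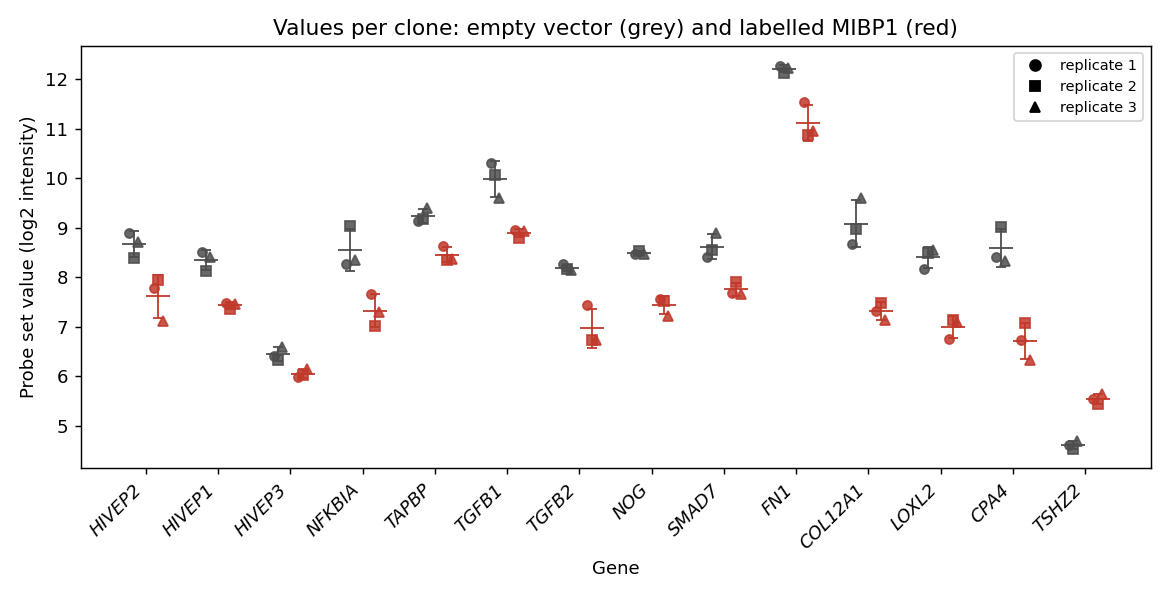
Log2 intensity of the probe set of 14 genes in each clone, with empty vector clones in grey and clones labelled MIBP1 in red; symbols mark replicates 1 to 3, and horizontal lines with bars give the mean and SD (n = 3). HIVEP2, HIVEP1 and HIVEP3 and the genes NFKBIA to CPA4 are lower in all 3 clones labelled MIBP1, and TSHZ2 is higher, at 5.54 against 4.61; none passed the adjusted threshold over all genes.

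The genes that were higher in the clones labelled MIBP1 differed by less. Apart from RCAN2 (7.5), the 12 named here had empty vector means of 4.3 to 6.1, against 8.2 to 12.2 for the 12 lower genes. Differences near the floor are compressed, so the sizes are not directly comparable. TSHZ2, a zinc finger transcription factor, went from 4.61 ± 0.08 (SD, n = 3) to 5.54 ± 0.10 (SD, n = 3), a difference of 0.93 (SE 0.15, limma adjusted p = 0.318). PVALB, which encodes the calcium-binding protein parvalbumin, gave 0.87 (SE 0.20), and SOX5, a transcription factor of neural and cartilage development, gave 0.82 (SE 0.19). RCAN2, a regulator of calcineurin, gave 0.72 (SE 0.17), DACH1, a transcriptional cofactor, gave 0.68 (SE 0.17), CDHR1, a cadherin-related protein, gave 0.69 (SE 0.17), and VWA5B2 gave 0.64 (SE 0.15). The noncoding transcripts SSBP3-AS1 and LINC00173 gave 0.74 (SE 0.18) and 0.66 (SE 0.17). IFNA6, AKR1C2 and CST1 gave 0.72, 0.72 and 0.79, but each belongs to a family with near-identical copies, so the gene behind the signal is uncertain. All 12 missed the threshold, with adjusted p of the other 11 between 0.731 and 0.843. All 12 had groups without overlap, which again adds little, as they were picked for the smallest p.

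Across the 18417 genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 952 genes, 536 higher and 416 lower, where 921 would pass by chance, and a test per gene without variance moderation gave 802 unadjusted and 1 after adjustment, C12orf75 at −0.30, which the rule for named genes does not cover. Among those 952 genes, 44 were lower and 4 higher by at least 2-fold. Among the 9209 genes at or above the median level, 65 were higher and 285 lower at an unadjusted p under 0.05. Together these are fewer than the share of 0.05 that passes by chance. Deviations sloped with mean level by 0.031, 0.030 and −0.005 in the empty vector clones. In the clones labelled MIBP1 the slopes were 0.022, −0.008 and −0.070. The direction among these brighter genes cannot be told apart from such slopes. The groups did not overlap in 2001 genes, 10.9% against the 10% that chance gives for 3 against 3. The unadjusted count rested on single clones: without empty vector replicate 2 it was 194 higher and 216 lower, and without MIBP1 replicate 1 it was 1428 higher and 790 lower. It also rested on the model. With the replicate block it was 1303 higher and 897 lower, and with the first residual component as a covariate 1829 and 1038. With array weights it was 2385 higher and 1853 lower. Weighting the arrays by their quality called 72 genes higher and 120 lower, from weights of 7.06 for MIBP1 replicate 2 and 0.292 for MIBP1 replicate 3.

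Target genes of NF-kB were lower as a group in the clones labelled MIBP1. Of 66 measured targets, 46 were lower and 20 higher, with a mean log2 difference of −0.20 (camera adjusted p = 2.02e-06). The call did not hold with an estimated correlation between genes (adjusted p = 0.308) or with fry (adjusted p = 0.369). At an unadjusted p under 0.05 there were 13 lower and 2 higher, 0 passed over all genes, and 5 passed when adjusted over the list alone, all lower. NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm, was 2.34-fold lower (−1.23, SE 0.24), and TAPBP, which encodes the peptide-loading protein tapasin, gave −0.78 (SE 0.16). IER3, a stress-induced survival gene, gave −0.67 (SE 0.17), and F3, which encodes tissue factor, gave −0.57 (SE 0.15). The 2 members higher at an unadjusted p under 0.05 were VCAM1 at 0.54 and CFLAR at 0.43, both named after their values were seen. The mean deviation of the list was 0.04, 0.27 and −0.003 in the empty vector clones and −0.14, −0.05 and −0.12 in the clones labelled MIBP1. Without 1 clone the adjusted p reached at most 0.00124, without MIBP1 replicate 1, and the mean was −0.12 without empty vector replicate 2.

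Components of the NF-kB pathway, its receptors, adaptors, kinases and subunits, were lower in 28 of 35 measured genes, with a mean of −0.17 (camera adjusted p = 3.99e-04, and adjusted p = 0.165 with an estimated correlation). NFKBIA passed when adjusted over the list alone. TNFAIP3, which encodes the inhibitor A20, gave −0.60 (SE 0.22) and −0.39 without empty vector replicate 2, and the adaptors TRAF3 and TRAF5 gave −0.42 (SE 0.18) and −0.47 (SE 0.20). NFKBIA and TNFAIP3 restrain the pathway and are also among its targets. The target list also holds BIRC2, CD40, CYLD, NFKB1, NFKB2, NFKBIE, REL, RELB and TNIP1. The call on components is therefore not separate from that on targets. No member was higher at an unadjusted p under 0.05, and 4 were lower.

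Response genes of TGF-beta and BMP were lower by a mean of −0.31 over 34 measured genes (camera adjusted p = 1.94e-07), with 23 lower and 11 higher. The call was lost with an estimated correlation (adjusted p = 0.0799) and with fry (adjusted p = 0.0718), while fry's test for changes in either direction gave an adjusted p of 0.00321. The estimated correlation of this list, −0.000967, was below the preset. When adjusted over the list alone 11 passed, 10 of them lower, and 0 passed over all genes. Besides NOG, TGFB2 and TGFB1, SMAD7, an inhibitory SMAD that TGF-beta induces, was 1.83-fold lower (−0.87, SE 0.17). ID3 at 0.86 and ID1 at 0.36, direct targets of BMP signalling, were the 2 members higher at an unadjusted p under 0.05, against 13 lower, and are named after their values were seen. The mean deviation of the list was 0.13, 0.24 and 0.10 in the empty vector clones and −0.17, −0.10 and −0.21 in the clones labelled MIBP1. Receptors and SMADs of these pathways differed less, with a mean of −0.10 over 18 genes, 15 of them lower (camera adjusted p = 0.0407, and adjusted p = 0.461 with an estimated correlation). Random lists matched on level had a mean of −0.06, and the list stood at percentile 18.4 among them. SMAD3 gave −0.49 (SE 0.17) and BMPR2, a BMP receptor, −0.35 (SE 0.15), while SMAD9 and TGFBR3 gave 0.31 (SE 0.15) and 0.30 (SE 0.15). The call on receptors and SMADs was lost without empty vector replicate 1 (0.105), empty vector replicate 3 (0.0583) or MIBP1 replicate 3 (0.313, with a mean of −0.05), and also after quantile normalization (0.208), with genes at or above the median level alone (0.124), with array weights (0.218) and after centring on neighbouring genes (0.144).

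Interferon-stimulated genes were lower in 37 of 40 measured members, with a mean of −0.57 (camera adjusted p = 3.81e-09, and adjusted p = 0.477 with an estimated correlation), but a single clone carried the difference. The mean deviation of the list was 1.34 in empty vector replicate 2 and 0.05 and −0.53 in the other 2 empty vector clones, against −0.18, −0.18 and −0.50 in the clones labelled MIBP1. Without empty vector replicate 2 the adjusted p was 0.357 and the mean −0.05, and without empty vector replicate 3 the mean was −0.98. DDX60, an antiviral helicase, had 6.02 ± 1.34 (SD, n = 3) with the empty vector and 4.92 ± 0.17 (SD, n = 3) in the clones labelled MIBP1. IFITM3 gave −0.91 (SE 0.38), IFITM2 −0.65 (SE 0.28) and HERC6 −0.68 (SE 0.29), with overlapping groups, and the IFITM genes are near-identical copies whose signals are uncertain. Without empty vector replicate 2, DDX60 gave −0.37, IFITM3 −0.39, HERC6 −0.40 and IFITM2 −0.42, and without MIBP1 replicate 3 IFITM2 gave −0.36. Without empty vector replicate 3, DDX60 gave −1.68 and HERC6 −1.02. When adjusted over the list alone 0 members passed.

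Genes of MHC class I presentation were lower in 11 of 12 measured members, with a mean of −0.57 (camera adjusted p = 6.94e-10, and adjusted p = 0.308 with an estimated correlation). TAP1 and TAP2, the subunits of the peptide transporter, gave −0.71 (SE 0.17) and −0.70 (SE 0.15). With TAPBP, these made 3 members that passed when adjusted over the list alone, and in all 3 the groups did not overlap. PSMB8, a subunit of the immunoproteasome, gave −1.08 (SE 0.41) with overlapping groups, and −0.60 without empty vector replicate 2. The mean deviation of the list was 0.27, 0.64 and −0.05 in the empty vector clones and −0.10, −0.31 and −0.44 in the clones labelled MIBP1. Without any 1 clone camera's adjusted p was at most 2.69e-07. The mean was −0.39 without empty vector replicate 2, the clone in which the interferon list stood at 1.34.

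**Figure D2:**
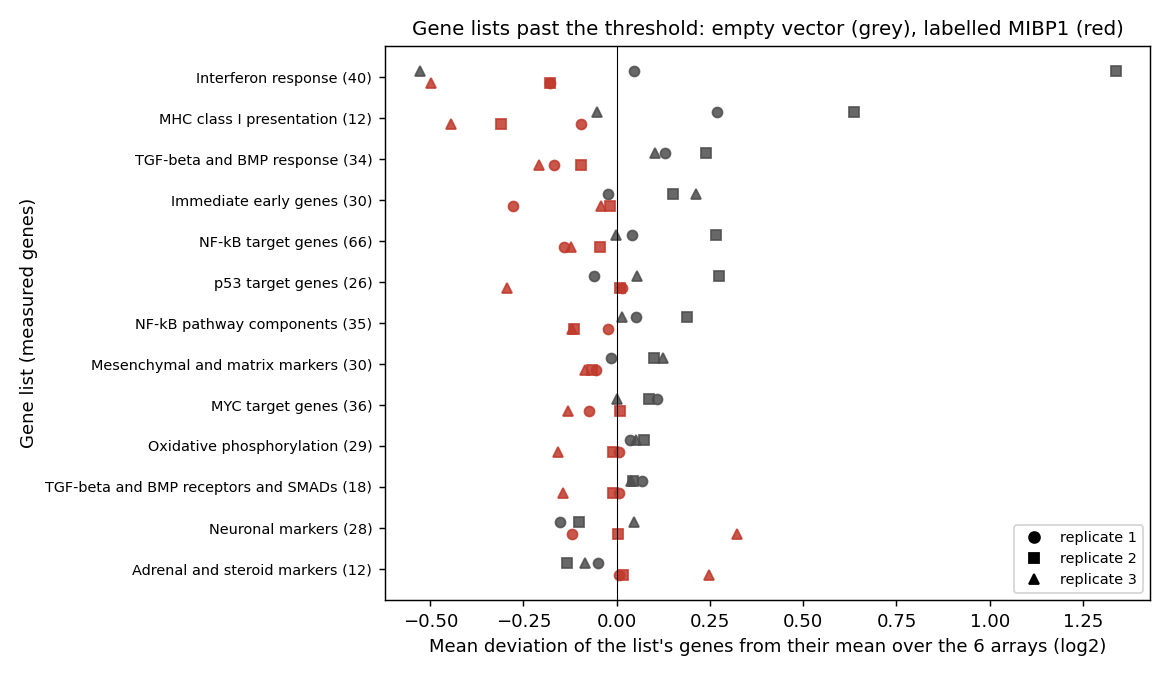
Mean deviation (log2) of each gene list's members from their means over the 6 arrays, 1 point per clone, for the 13 lists past the camera threshold; empty vector clones are grey, clones labelled MIBP1 are red, symbols mark replicates 1 to 3, and the number of measured genes is in brackets. The interferon list stands at 1.34 in empty vector replicate 2, and the neuronal and adrenal lists stand at 0.32 and 0.25 in MIBP1 replicate 3.

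Immediate early genes, the rapid response to serum and stress, had a mean of −0.23 over 30 genes, 21 of them lower (camera adjusted p = 4.83e-05, and adjusted p = 0.369 with an estimated correlation). CCN1, a matrix-associated signalling protein, was 2.11-fold lower (−1.08, SE 0.25), and with IER3 it made 2 members that passed when adjusted over the list alone. DUSP1, a MAP kinase phosphatase, gave −0.87 (SE 0.35), and −0.40 without MIBP1 replicate 3, and the transcription factor ATF3 gave −0.52 (SE 0.18). The call was lost without MIBP1 replicate 1 (0.0685, with a mean of −0.14) and with array weights (0.0661).

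Target genes of p53 were lower in 22 of 26 members, with a mean of −0.18 (camera adjusted p = 5.98e-04, and adjusted p = 0.476 with an estimated correlation). TP53I3 gave −0.76 (SE 0.21), CDKN1A, which encodes the cell cycle inhibitor p21, gave −0.41 (SE 0.16), and the death receptors FAS and TNFRSF10B gave −0.55 (SE 0.24) and −0.48 (SE 0.19). MYC target genes were lower in 31 of 36 members, with a mean of −0.13 (camera adjusted p = 3.23e-04, and adjusted p = 0.369 with an estimated correlation). Among random lists matched on level, with a mean of −0.07, it stood at percentile 2.62. CAD, an enzyme of pyrimidine synthesis, gave −0.46 (SE 0.21), the ribosome assembly factor UTP20 −0.35 (SE 0.17), the transferrin receptor TFRC −0.32 (SE 0.18), and TERT, the telomerase subunit, 0.31 (SE 0.16). Nuclear genes of oxidative phosphorylation were lower in 24 of 29 members, with a mean of −0.11 (camera adjusted p = 0.0132, and adjusted p = 0.369 with an estimated correlation). Its matched random lists had a mean of −0.08, and it stood at percentile 17.7 among them. NDUFV1 gave −0.41 (SE 0.21), COX4I1 −0.29 (SE 0.17), NDUFS3 −0.30 (SE 0.23) and SDHD −0.30 (SE 0.26), the last with pseudogene copies that make its signal uncertain. In these 3 lists 0 members passed when adjusted over the list alone. The array of MIBP1 replicate 3 had the narrowest spread of values, with a log2 quartile range of 3.49 against 3.67 to 3.86 in the others, and it had the lowest mean deviation in each of the 3 lists, −0.29, −0.13 and −0.16. Without it the mean was −0.08 for p53 targets and −0.06 for oxidative phosphorylation, and the adjusted p was 0.143 and 0.175. Without empty vector replicate 2 the mean of p53 targets was −0.09. Single clones also moved members: FAS gave −0.30 and NDUFV1 −0.21 without empty vector replicate 2, CAD −0.26 and COX4I1 −0.15 without empty vector replicate 3, and UTP20 −0.22, TFRC −0.20, NDUFS3 −0.13 and SDHD −0.11 without MIBP1 replicate 3. NDUFS3 and SDHD also gave −0.17 and −0.17 without empty vector replicate 2, but −0.46 and −0.56 without MIBP1 replicate 1 and −0.49 and −0.50 without empty vector replicate 3. Both calls on p53 targets and oxidative phosphorylation were also lost with genes at or above the median level alone (0.0813 and 0.352) and with array weights (0.293 and 0.179), and that on oxidative phosphorylation after quantile normalization (0.165).

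Mesenchymal and matrix markers went both ways. The 30 genes had a mean of −0.14 and a median of 0.04, which differ in sign, with 14 lower and 16 higher (camera adjusted p = 0.0397, and adjusted p = 0.369 with an estimated correlation). At an unadjusted p under 0.05 there were 9 lower and 0 higher, and FN1 passed when adjusted over the list alone. LOX, another collagen cross-linking enzyme, gave −1.01 (SE 0.32) and −0.60 without empty vector replicate 2, COL4A1, a basement membrane collagen, −0.51 (SE 0.15), and CNN1, a smooth muscle calponin, −0.59 (SE 0.18). The call was lost without empty vector replicate 3 (0.162) or MIBP1 replicate 1 (0.164), with array weights (0.243), after centring on neighbouring genes (0.0606), with the first residual component as a covariate (0.184) and on ranks (0.458).

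Neuronal and adrenal markers were the 2 lists that were higher. Neuronal markers were higher in 23 of 28 genes, with a mean of 0.14 (camera adjusted p = 0.0134, and adjusted p = 0.657 with an estimated correlation). SCG3, a granin of secretory vesicles, gave 0.83 (SE 0.30), MAP2, a dendritic microtubule protein, 0.70 (SE 0.26), the synaptotagmin SYT4 0.58 (SE 0.23) and STMN3 0.49 (SE 0.18), while the neurofilament gene NEFM, named after its value was seen, stood at −1.60. Adrenal and steroid markers were higher in 11 of 12 genes, with a mean of 0.18 (camera adjusted p = 0.0134, and adjusted p = 0.461 with an estimated correlation). The steroid enzymes CYP17A1 and CYP11B1 gave 0.40 (SE 0.15) and 0.39 (SE 0.19), TH gave 0.29 (SE 0.16) and FDX1 −0.38 (SE 0.22), and CYP11B1 has a near-identical neighbour that makes its signal uncertain. Random lists matched on level had means of 0.07 and 0.10, and the neuronal and adrenal lists stood at percentiles 93.0 and 88.2 among them. Both lists stood highest in MIBP1 replicate 3, the array with the narrowest spread, at 0.32 and 0.25, where leukocyte markers, which a kidney line should lack, stood at 0.18. Without that clone the mean was 0.01 for neuronal and 0.10 for adrenal markers, CYP11B1 gave 0.21 and FDX1 −0.23, and the lists' adjusted p was 0.569 and 0.139. Without MIBP1 replicate 1 the neuronal mean was 0.23, without MIBP1 replicate 2 SCG3 gave 0.48, and without empty vector replicate 3 FDX1 gave −0.60. After quantile normalization the adjusted p was 0.106 for neuronal and 0.0961 for adrenal markers. The neuronal call was also lost without empty vector replicate 1 (0.0915) and with genes at or above the median level alone (0.124), and the adrenal call without empty vector replicate 3 (0.0583) and with array weights (0.293).

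The other 14 lists missed the threshold. Camera's adjusted p was 0.0906 for cell cycle inhibitors and D cyclins, 0.0958 for integrins and adhesion, 0.126 for DNA replication, 0.225 for leukocyte markers, 0.252 for Wnt response, 0.252 for the hexosamine pathway, 0.278 for apoptosis regulators and 0.278 for mitosis. It was 0.387 for glycolysis and hypoxia, 0.643 for Notch response, 0.770 for kidney and epithelial markers, 0.811 for the unfolded protein response, 0.872 for cholesterol synthesis and 0.918 for heat shock. In these 14 lists 0 members passed when adjusted over the list alone. Some passed in other settings: integrins and adhesion after quantile normalization (0.0356), without MIBP1 replicate 3 (0.0344) and among genes at or above the median level (2.45e-05), which also brought in the unfolded protein response (0.0385). DNA replication passed without empty vector replicate 3 (0.0281) or MIBP1 replicate 1 (0.00790), mitosis without empty vector replicate 3 (0.0382), MIBP1 replicate 1 (0.0456) or MIBP1 replicate 2 (0.0465), and the hexosamine pathway without empty vector replicate 3 (0.0470). Cell cycle inhibitors passed without empty vector replicate 2 (0.0418) or MIBP1 replicate 2 (0.0355), and Wnt response and cholesterol synthesis without MIBP1 replicate 3 (0.0229 and 0.0189). With an estimated correlation or with fry 0 of the 27 lists passed, and 1 passed fry's test for changes in either direction, TGF-beta and BMP response.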

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

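Tests chosen only after the result was seen are those on exchanged labels for HIVEP2 and the centring on neighbouring genes. They include those on the narrow array for the NF-kB list and for the 4 lists named with it. Those on other splits for the NF-kB, TGF-beta and MHC class I lists were also chosen after it.

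A probe set without a gene name, 7895352, which the comparisons of genes leave out, was lower in the clones labelled MIBP1 by a log2 difference of −2.88 (limma adjusted p = 0.00373 over all 33297 probe sets), at 5.22, 4.84 and 4.86 with the empty vector and 2.28, 2.03 and 1.99 in the clones labelled MIBP1. Whether it measures a transcript or is a control of the array is not given in the sources used here.

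The camera test called 13 lists where 0 genes passed: after quantile normalization, which gives MIBP1 replicate 3, the array with the narrowest spread, the same distribution as the others, 9 of the 13 lists were still called in the same direction, and 8 of the 13 lay outside the central range of random lists matched on level, the other 5 being MYC targets, TGF-beta receptors, oxidative phosphorylation, neuronal and adrenal markers; both counts fall between the bounds set beforehand, so neither account can be told apart from a real shift for the lists as a whole. The narrow array is argued against for the NF-kB list, with an adjusted p of 3.13e-08 after quantile normalization, and stays open for the neuronal, adrenal, oxidative phosphorylation and TGF-beta receptor lists, as these 4 were picked because that setting ended their calls and the count of 0 left decides nothing. The interferon call is consistent with 1 array alone, as leaving out empty vector replicate 2 gave 0.357, whereas the NF-kB list reached at most 0.00124 without any 1 array, though its mean went from −0.20 to −0.12 without that same clone, and 11 of the 13 calls were left after centring on neighbouring genes, which argues against copy number as the whole cause. The 10 splits of the arrays into 3 and 3 are too few for a share under 0.05. Of these, 2, the real one included, gave at least the real 13 lists. Every other split, though it mixes the groups, called lists at the preset correlation, 5 to 14 of them. For the NF-kB list (2.02e-06) and the TGF-beta and BMP list (1.94e-07) only 1, the real one, reached its adjusted p. Mixed splits still called the NF-kB list, at 1.78e-04, 1.80e-04 and 5.48e-04, and the TGF-beta and BMP list, at 0.00672, 0.0129 and 0.0203. They also called the MHC class I list, at 5.22e-05, 1.57e-04, 5.55e-04 and 7.33e-04, against a camera adjusted p of 6.94e-10 in the real split. The interferon list went the other way, with 3.81e-09 in the real split and down to 1.20e-19 in mixed ones. An effect of MIBP1 itself stays open, untested apart from these.

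HIVEP2 was lower in the clones labelled for its overexpression. The values of HIVEP2 cannot decide on an exchange of single arrays between the groups. That 0 arrays lay among the values of the other group restates the difference, and the probe set may check nothing about the labels. A lower copy number of that part of the chromosome is argued against by a difference of −0.998 after centring on neighbouring genes, against −1.05 before. An exchange of all labels, and a lower level of the cells' own transcript with the transgene unseen by the probes, cannot be told apart from the difference of −1.05, because no probe is known to lie in the transgene.

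The arrays held a structure that crosses the groups. Empty vector replicates 1 and 2 with MIBP1 replicate 1, against the other 3 arrays, gave 4071 genes at an unadjusted p under 0.05, where the real split gave 952 and 3 of the 10 splits, the real one included, gave at least as many; at the adjusted threshold the highest other split gave 14 genes and the real one 0, a number that 10 of 10 splits, the real one included, reach, and 10 splits are too few for a share under 0.05. The split still gave 3783 genes after centring on neighbouring genes, which argues against copy number as its whole cause. After quantile normalization it gave 3470, which cannot decide on the narrow array, as the slopes on mean level still separated the 2 sets. In empty vector replicates 1 and 2 and MIBP1 replicate 1 the slopes were 0.031, 0.030 and 0.022 before and 0.012, 0.011 and 0.010 after. In empty vector replicate 3 and MIBP1 replicates 2 and 3 they were −0.005, −0.008 and −0.070 before and 0.0006, −0.006 and −0.028 after. In all 6 arrays the largest running median over neighbouring genes was above the highest of 100 shuffles of the gene order. Copy number changes that single clones carry would give such runs. The strongest was 0.65 above the other 5 arrays in MIBP1 replicate 3, in a run from IQCN to ZNF611. The next was 0.62 in empty vector replicate 2, in a run from KRTAP5-1 to B3GAT1. As each array was set against the other 5, a shift in 1 array moves the rest the opposite way. The largest of empty vector replicate 3, −0.39, peaked at the same gene, ENDOD1, as that of empty vector replicate 2. The 6 arrays are therefore not 6 separate findings, and shifted runs of any array held 8368 of the 13774 ordered genes. Shared regulation of neighbouring genes was not tested, and the design gives no biological explanation for the split, so none was tested.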

How the results depend on the processing

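The centring on neighbouring genes and the residual component as a covariate were chosen after seeing the data. Calls of single genes moved in 4 settings: array weights gave 72 higher and 120 lower, the replicate block 3 lower, all probe sets 1 lower (the unnamed 7895352) and the test without variance moderation 1 lower. The array weights, 7.06 for MIBP1 replicate 2, had not converged, and the cause of these changes was not tested. In every other setting, each clone left out included (0 to 0), 0 genes were called. The NF-kB list lost its call with an estimated correlation (adjusted p = 0.308) and with fry (0.369), and ran from 4.43e-07 to 0.00124 without single clones and from 3.13e-08 to 0.00175 in the other settings. The lists called numbered 7 with array weights, 0 with an estimated correlation and 0 with fry, 11 to 15 without single clones, and 10 to 13 otherwise. Against the preset 0.01, the estimated correlation was 0.0658 for the NF-kB list and 0.750 for the interferon list, but 0.00210 for NF-kB pathway components and −0.000967 for TGF-beta and BMP response, so for the last 2 it did not end the call; that test also works from 4 residual degrees of freedom. Adrenal and leukocyte markers had under 5 genes at or above the median level and were not tested there. Of 466 alternatives for the other lists 70 changed the call, and 0 reversed a call. All 1037 alternatives for the 71 named genes had the same sign, and 31 of these genes were called with array weights. Part of that shared sign was fixed in advance, as the genes were picked on the same arrays. An intensity trend, the replicate block and the residual component also leave each difference unchanged. Leaving out 1 clone moved the size by over 1.5 times in 19 of the 71, all of them members of lists.

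The values do not settle whether replicate numbers pair the clones. The correlation of deviations across genes was 0.374, 0.0469 and 0.542 for replicates 1, 2 and 3. Empty vector replicates 1 and 3 correlated best with the MIBP1 clone of the same number. Empty vector replicate 2 correlated best with MIBP1 replicate 1 (0.260). These 2 and empty vector replicate 1 form one side of the split with 4071 genes. The correlations are therefore not separate from the structure that crosses the groups. With the replicate block, CPA4, LOXL2 and TFPI2, the last named after its values were seen, were called lower, 0 genes higher and 12 lists, the mesenchymal list being lost. Signal over background is unknown, so dim genes cannot be set apart, and 3 clones per group leave a median SE of 0.181.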

Other observations

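The test on target genes of YAP and TEAD was chosen after the genes with the smallest p were seen, and its bounds were written before the list's values.

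The lower genes with the smallest p all missed the adjusted threshold. They led to the hypothesis that the output of YAP and TEAD may be lower in the clones labelled MIBP1. YAP and TEAD are regulators of transcription that respond to cell tension and density. Over 18 of their target genes, leaving out 4 whose values had been seen, the mean log2 difference was −0.28 and the median −0.28, with 15 genes lower, and without single clones the mean ran from −0.32 to −0.23. At an unadjusted p under 0.05 there were 5 lower and 0 higher: CCN2, a matrix-associated protein, at −1.09 (SE 0.33), CRIM1 at −0.57 (SE 0.16), AMOTL2, an angiomotin that restrains YAP, at −0.48 (SE 0.20), FJX1 at −0.44 (SE 0.19) and PTPN14 at −0.39 (SE 0.16). Fry in limma gave a p of 0.00783 for a shift one way and camera with an estimated correlation a p of 0.00936. Neither was adjusted for the lists tested before. The hypothesis came from the same arrays, so targets that move together with the genes seen are not separate evidence. This list was not set against matched random lists or other splits. The values are consistent with the hypothesis, but CCN2 is also in the TGF-beta and BMP list and GADD45A in the p53 list, and a difference in density or growth between clones was not measured.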
